A study of Rattus norvegicus with 14 samples.

How the data were processed

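RNA of rat liver, from the left lateral lobe, was measured on an Affymetrix rat oligonucleotide array with 8799 probe sets. Per the labels, about 5 µg of total RNA went into each target, and the 14 arrays fell into 3 diets: 5 magnesium-supplemented, 5 standard and 4 magnesium-deficient. The diet and the array number were read from the sample titles. Numbers ran on from diet to diet, so no number was shared between diets. The deposited values are intensity values (probe set signals on a linear scale). The software that made the signals, its settings and any detection calls are not given in the sources used here. In the deposited intensity table every array had a mean signal of 150.3 units after the top and bottom 2% were trimmed, so the arrays carried a common global scaling. The signals ran from 0.0104 to 16556 units. No pair of arrays held identical values, and no data column was left unused.

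The array medians nevertheless differed by up to 1.91 times. A limit of 1.5 times had been set before the data were examined, above which arrays were to be quantile normalised, and this was done on the log2 scale over the probe sets other than controls. Normalised signals below the pooled 20th percentile, 3.93 units, were set to that floor and log2 was taken. The 59 Affymetrix control probe sets were left out. Probe sets were kept when their mean over all arrays was above the pooled 40th percentile, 3.83 on the log2 scale or 14.3 units. This left 5132 probe sets and 3073 genes. Gene symbols came from the platform annotation supplied with the table. Of the probe sets other than controls, 7006 had 1 symbol, 308 had several and 1426 had none, and the symbols of 6985 were found in the current rat gene table. No gene was named from a probe set with several symbols. Without detection calls, whether a dim signal lay above background is unknown, and the number of arrays limits the precision of every value.

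Differences between diets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the spread on the mean) in 1 model of the 3 diets, so that all 14 arrays gave 1 estimate of the spread. The moderated F-test of the fit asked for any difference among the diets. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. All p-values are two-sided. Fold changes are on the log2 scale of floored signals and understate changes of dim probe sets. For gene lists and named genes, the probe set with the highest mean over the 14 arrays stood for each gene.

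Before the data were examined, 42 gene lists were fixed for liver metabolism, magnesium and ion transport, stress, inflammation and the cell types a liver sample can hold. The 40 with at least 5 measured genes were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the 40 lists of a comparison. Camera with a correlation estimated from the data, and fry, stood beside it. The score of a list on an array was the mean deviation of its genes from their 14-array means. Scores and array measures were compared by exact permutation tests, whose smallest possible p was 0.00794 in each of the 3 comparisons.

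Named genes followed a rule also fixed beforehand. It took up to 10 rises and 10 falls among called genes whose arrays did not overlap between diets or, with fewer than 5 such genes, the 5 with the smallest p. It added the 4 members with the smallest p of each called list, at most 1 member of each other list and 3 members of the magnesium transport list. After the data were seen this was narrowed: members of uncalled lists are named only at an unadjusted p under 0.05, and not all of those, while the magnesium list always gives its 3.

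The procedure was tested on simulated data made from the 5132 probe sets with 200 changed in each of 10 runs. In the deficient against standard comparison 54.6% of 2-fold changes, 92.8% of 4-fold changes and 98.6% of 8-fold changes were recovered. For supplemented against standard these were 60.5%, 95.1% and 98.8%, and for deficient against supplemented 52.7%, 92.8% and 98.8%. False calls made up 3.98%, 3.97% and 4.46% of calls. A list of 15 genes among 3073, shifted by 0.5 on the log2 scale, was called in 10 of 10 runs in each comparison. The simulated probe sets and genes varied independently of one another, whereas genes of a list can vary together on real arrays. For the cholesterol synthesis list the correlation estimated between genes was 0.434 for deficient against standard. The runs therefore do not show how often such lists or probe sets are called falsely. The shares recovered hold for runs with 200 changed probe sets, where many small p-values make the adjusted threshold easier to reach. They do not show what share would be recovered if few probe sets changed. On the real arrays Crispld2, 3.24-fold lower on the supplemented than on the standard diet, missed the threshold (limma adjusted p = 0.0502).

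Alternatives covered the scaling between arrays, the floor, the filter, the model of the spread, array weights, the arrays in the fit, the 3'/5' signal ratio of the Gapdh control as a covariate, a fold minimum of 1.5, other list tests, and leaving out each array in turn. The overlap between comparisons that share the standard arrays was set beside 1000 simulations of unchanged diets, and the probe sets past an unadjusted p in both beside 100. Other splits of the arrays were drawn 100 at a time, the real split included.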

Results

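The series measured liver gene expression in rats fed a magnesium-supplemented, a standard or a magnesium-deficient diet. Liver from the left lateral lobe gave 14 arrays, 5 for the supplemented diet, 5 for the standard diet and 4 for the deficient diet. The labels give neither the magnesium content of the diets nor their duration, nor the sex of the animals. They also do not say whether each array came from a separate animal, so p-values measure only the spread between these samples. Median signals ran from 18.0 units (deficient array 13) to 34.4 units (supplemented array 5). Across arrays, the mean rank correlation of an array with the other 13 lay between 0.940 and 0.951 except for supplemented array 5, at 0.913.

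Signs of RNA quality went along with diet at an unadjusted p. Affymetrix control probe sets at both ends of the Gapdh and beta-actin transcripts give a 3'/5' signal ratio that rises as RNA is degraded or incompletely copied. The log2 Gapdh ratio was 0.71 ± 0.49 (SD, n = 5) on the supplemented diet, 1.64 ± 0.61 (SD, n = 5) on the standard diet and 1.84 ± 0.65 (SD, n = 4) on the deficient diet. The supplemented diet lay below the standard diet by an exact permutation test (p = 0.0159) and below the deficient diet (exact permutation p = 0.0159). Both adjusted values were 0.0952 over a family of 18 comparisons of array measures. For beta-actin the deficient minus supplemented difference was 0.89 on the log2 scale (exact permutation p = 0.0476, adjusted 0.171). The supplemented minus standard difference was -0.56 and did not pass unadjusted (exact permutation p = 0.103, adjusted 0.310). Supplemented array 5, with the lowest Gapdh ratio, had the highest beta-actin ratio of the supplemented arrays (1.29 on the log2 scale). The first principal component, which held 21.1% of the variance, followed the log2 Gapdh ratio over the 14 arrays with Pearson's r = 0.951 and Spearman's rho = 0.930 (permutation p = 1e-05 for each, the smallest that the resamples can give, and 2e-05 after adjustment over 2 relations). Without deficient array 13 and standard array 10, the farthest from the median ratio, r was 0.943. Within diets, after each diet's mean was taken out, r was 0.904 (permutation p = 1e-05). For the beta-actin ratio r was 0.817 (permutation p = 2e-04), rho was 0.842 (permutation p = 3e-04), and r without those arrays was 0.716.

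**Figure D1:**
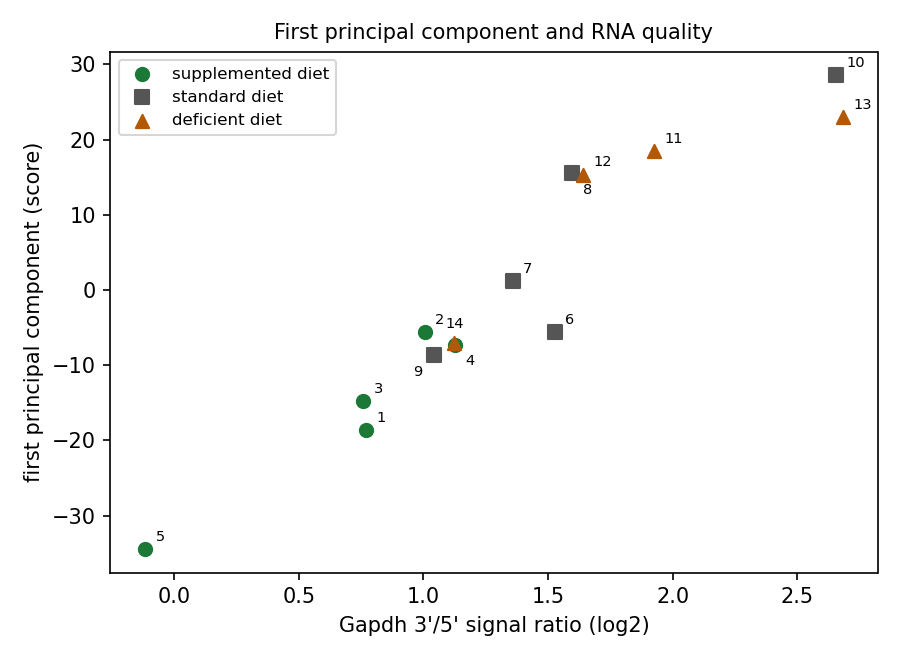
First principal component score of each of the 14 arrays against the log2 Gapdh 3'/5' signal ratio, with a point per array, numbered as in the labels, and a symbol per diet. Supplemented array 5, at a ratio of -0.12 and a score of -34.4, and standard array 10, at 2.65 and 28.5, lie at opposite ends of the relation.

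The deficient diet was first compared with the standard diet, which asks how liver transcripts differ on a diet labelled magnesium-deficient. Genes of cholesterol synthesis rose as a group: all 15 measured members were higher on the deficient diet, by a mean of 0.52 on the log2 scale or 1.44-fold (camera adjusted p = 1.15e-07; adjusted p = 0.711 with an estimated correlation). Ebp, a sterol isomerase, was 0.50 ± 0.15 higher (SE), Msmo1, which removes methyl groups from sterols, 0.67 ± 0.29 higher, Hsd17b7 0.70 ± 0.33 higher and Nsdhl 0.40 ± 0.18 higher. None of these single genes passed limma's test (adjusted p = 0.999 for Ebp, Msmo1 and Nsdhl), and 0 of the 15 passed when adjusted over the list alone. The score of the list was 0.22 ± 0.25 (SD, n = 4) on the deficient and -0.30 ± 0.59 (SD, n = 5) on the standard diet (exact permutation p = 0.159). On the standard diet it ranged from -1.04 (array 8) and -0.74 (array 7) to 0.44 (array 9). With 1 array left out the mean shift ran from 0.33 (standard array 8, adjusted p = 0.00143) to 0.71 (standard array 9, adjusted p = 4.42e-13), called each time. These runs kept camera's preset correlation, whereas 0.434 was estimated for this list. Msmo1 was at 0.44 without deficient array 14, and Nsdhl at 0.26 without standard array 8.

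Cytosolic ribosomal protein genes rose slightly, with 34 of 39 members higher and a mean of 0.11, or 1.08-fold (camera adjusted p = 0.0107; adjusted p = 0.848 with an estimated correlation). Rpsa was 0.24 ± 0.13 (SE) higher, Rpl36 0.27 ± 0.17, Rpl41 0.32 ± 0.20 and Rps10 0.17 ± 0.11, none past the test. This call was lost without standard array 6 (0.097, adjusted p = 0.0656) or 9 (0.071, adjusted p = 0.0983). Without standard array 6 Rpl36 was at 0.17 and Rpl41 at 0.18, and Rpl41 was at 0.21 without standard array 9. Cytosolic and mitochondrial heat shock protein genes fell by a mean of 0.24, with 12 of 15 members lower (camera adjusted p = 0.0285; adjusted p = 0.711 with an estimated correlation). Examples were Hspa9, a mitochondrial chaperone, at -0.43 ± 0.25 (SE), the co-chaperones Stip1 at -0.38 ± 0.25 and Dnaja1 at -0.35 ± 0.25, and the small heat shock protein Hspb1 at -0.76 ± 0.54. Only 1 of the 2 tested probe sets of Dnaja1 was lower, whereas all 2 of Hspa9 and all 4 of Hspb1 were. Without the 3 arrays that stood apart in RNA quality or correlation (supplemented 5, standard 10 and deficient 13) the heat shock shift was -0.085 (adjusted p = 0.245) and Hspb1 turned to 0.052. Single arrays whose omission ended the call were standard 9 and 10 and deficient 13 and 14, with shifts of -0.25, -0.15, -0.18 and -0.19. Hspb1 was at -0.30 without standard array 10 and -0.41 without deficient array 13. Dnaja1 was at -0.19 and Stip1 at -0.59 without deficient array 14, and Dnaja1 at -0.59 without deficient array 11. The beta-actin ratio as a covariate put Stip1 at -0.24. Markers of neighbouring tissue, meaning pancreas, fat and muscle, fell by a mean of 0.20, with 10 of 12 lower (camera adjusted p = 0.0448; adjusted p = 0.848 with an estimated correlation). They included the pancreatic genes Ins2 at -0.62 ± 0.32 (SE), Clps at -0.56 ± 0.34 and Amy2a3 at -0.38 ± 0.23, and the fat hormone gene Lep at -0.55 ± 0.29. Clps was at -0.30 without deficient array 12. In each of these 3 lists 0 genes passed when adjusted over the list alone. The Gapdh 3'/5' ratio of the deficient and standard arrays differed by 0.21 on the log2 scale (exact permutation p = 0.595), and with it as a covariate the neighbouring tissue shift was -0.16 (adjusted p = 0.111). That list's call was also lost without supplemented array 3, any 1 of the 5 standard arrays, or deficient array 13 or 14, with shifts from -0.23 to -0.14, and with no filter on dim probe sets (-0.11, adjusted p = 0.368). With arrays centred on their median, the ribosomal, heat shock and neighbouring tissue calls all ended.

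At the level of single probe sets, limma called 0 of 5132 between the deficient and the standard diet. At an unadjusted p under 0.05 there were 154, of which 67 were higher and 87 lower, where chance gives 256.6. There were 92 without deficient array 13. The 5 genes with the smallest p, which did not pass (adjusted p = 0.999 for each), were Scn4a, a sodium channel gene, at -1.38 ± 0.33 (SE), the deacetylase gene Hdac6 at 0.71 ± 0.17, Clec11a at 1.48 ± 0.39, the growth factor gene Fgf2 at -1.15 ± 0.32 and Pstpip1 at 1.01 ± 0.28. Pstpip1 lay under the level of the dim-probe filter on 4 of 5 standard arrays and Clec11a on 3. Of the other lists, 36 were not called. Their members with the smallest p included Sod3, an extracellular superoxide dismutase, at -0.70 ± 0.20 (SE), the interferon-induced Mx2 at -1.25 ± 0.46, the calcium release channel gene Itpr3 at -0.58 ± 0.21, Myc at 0.63 ± 0.26, Racgap1 at -0.48 ± 0.21 and Cbs, which makes cystathionine, at 0.44 ± 0.19. None of them passed (adjusted p = 0.999). Without deficient array 11 Mx2 was at -0.66, without deficient array 13 Cbs was at 0.29, and without the 3 arrays that stood apart Myc was at 0.32.

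The magnesium transport list, with 6 measured genes, was not called here (mean -0.12, adjusted p = 0.521, 5 of 6 lower). Its members with the smallest p were Slc41a3, a magnesium carrier, at -0.43 ± 0.33 (SE), Egf at -0.15 ± 0.25 and Cnnm4 at 0.14 ± 0.27. Without deficient array 14, Slc41a3 turned to 0.023, and it was at -0.67 without deficient array 11 and -0.24 with array weights. Egf was at -0.021, -0.045 and -0.37 without deficient arrays 11, 12 and 14, and Cnnm4 lay between 0.014 (without standard array 6) and 0.28 (without standard array 10). Both differences were smaller than their SE and moved widely in other settings too. The list mean was -0.071 with no filter.

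**Figure D2:**
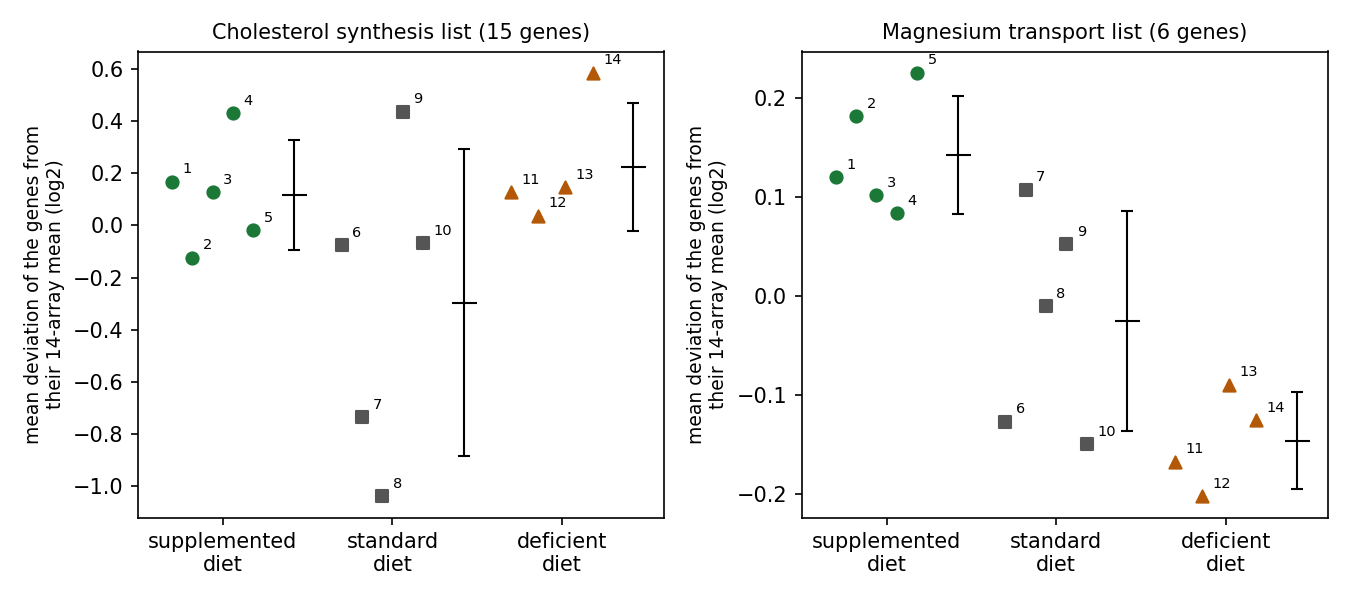
Scores of the cholesterol synthesis list (left) and the magnesium transport list (right) on each array, as the mean log2 deviation of the list's genes from their 14-array means. Each point is 1 array, numbered as in the labels, and bars give the mean and SD per diet. Standard arrays 7 and 8 have the lowest cholesterol scores, -0.74 and -1.04, and the magnesium scores average -0.15 on the deficient and 0.14 on the supplemented diet.

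The supplemented diet was then compared with the standard diet, to see what extra magnesium does. Cholesterol synthesis genes were again higher, with 13 of 15 members up and a mean of 0.41 or 1.33-fold (camera adjusted p = 0.00122; adjusted p = 0.944 with an estimated correlation). Ebp was 0.42 ± 0.14 (SE) higher, Idi1 1.08 ± 0.56, Sqle, an early rate-controlling oxygenase of the sterol branch, 0.95 ± 0.51, and Acat2 0.71 ± 0.40, none past limma's test. The standard arrays are the reference of this comparison too. Leaving out standard array 8 alone gave a shift of 0.23 (adjusted p = 0.190), with Sqle at 0.55 and Acat2 at 0.40, while leaving out standard array 9 gave 0.60 (adjusted p = 1.09e-06). Acat2 was at 0.45 without standard array 7. The beta-actin ratio as a covariate put Idi1 at 0.52 and Sqle at 0.53, and arrays centred on their median put Ebp at 0.28. Markers of Kupffer cells and macrophages rose by a mean of 0.24, with 10 of 11 higher (camera adjusted p = 0.0191; adjusted p = 0.944 with an estimated correlation). Clec4f, a lectin of Kupffer cells, was 0.37 ± 0.15 (SE) higher, Cd53 0.73 ± 0.34, Fcgr2b 0.32 ± 0.18 and Cyba 0.32 ± 0.21. In both lists 0 genes passed when adjusted over the list alone. The supplemented arrays had the lower Gapdh 3'/5' ratio, by 0.93 on the log2 scale, and with the ratio as a covariate the macrophage shift was 0.26 (adjusted p = 0.0594) and Fcgr2b was at 0.089. With the beta-actin ratio the shift was 0.16 (adjusted p = 0.126) and Fcgr2b was at 0.11. Fcgr2b was at 0.20 without standard array 10. That call was also lost without supplemented array 1 (0.20, adjusted p = 0.129), supplemented array 4 (0.18, adjusted p = 0.163), standard array 6 (0.21, adjusted p = 0.110) or standard array 8 (0.21, adjusted p = 0.128). Supplemented array 5 went the other way, with the lowest macrophage score of all arrays (-0.32). Without it the shift was 0.35 (camera adjusted p = 0.00095).

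Limma called 0 of 5132 probe sets between the supplemented and the standard diet. At an unadjusted p under 0.05 there were 457 (213 higher, 244 lower), where chance gives 256.6. With the Gapdh ratio as a covariate there were 132, and without standard array 10 there were 287. The smallest p belonged to Crispld2, which encodes a secreted cysteine-rich protein, at -1.70 ± 0.26 (SE) or 3.24-fold lower, just short of the threshold (adjusted p = 0.0502). The next were Ssh3, a cofilin phosphatase gene, at 1.09 ± 0.25 (SE), Clec11a at 1.63 ± 0.37, Coro7 at -0.74 ± 0.17 and Lrrc8a, a subunit of volume-regulated anion channels, at -2.25 ± 0.57. None of these 4 passed (adjusted p = 0.379 for Ssh3, Clec11a and Coro7, 0.479 for Lrrc8a), and Clec11a was at 1.04 with the Gapdh ratio as a covariate. Lrrc8a was at the floor on 4 of 5 supplemented arrays and at 5.45 on the fifth, array 2; without that array its difference was -2.95 (adjusted p = 0.00056), measured against the floor.

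Of the other lists, 38 were not called in this comparison. Members with the smallest p, none of which passed, included several liver enzymes and transporters. The arginine transporter gene Slc7a2 was at -0.84 ± 0.23 (SE), the bile salt pump gene Abcb11 at 0.57 ± 0.20, the glutathione transferase gene Gsta1 at 0.39 ± 0.13, the translocon gene Sec61b at 0.41 ± 0.13 and the peroxisomal thiolase gene Acaa1b at -0.63 ± 0.23. The stress transcription factor gene Ddit3 was at -1.24 ± 0.45, the calcium pump gene Atp2b1 at -1.11 ± 0.39, Cish at 1.30 ± 0.50, Hgf at -1.25 ± 0.44 and the clock gene Bhlhe40 at 0.59 ± 0.21. Atp2b1 was at -0.67 without supplemented array 3, and Hgf at -0.80 without supplemented array 5, which was at the floor. The Gapdh ratio as a covariate put Ddit3 at -0.56, Hgf at -0.50 and Gsta1 at 0.24. Without the 3 arrays that stood apart Ddit3 was at -0.80 and Hgf at -0.68. With arrays centred on their median Gsta1 was at 0.22 and Sec61b at 0.27. Secreted plasma proteins were represented by Mug1 at 1.87 ± 0.74, Plg at 1.04 ± 0.43 and Fgb at 0.35 ± 0.14. With the Gapdh ratio as a covariate Plg turned to -0.031, Mug1 fell to 0.00034 and Fgb to 0.12. With the beta-actin ratio they were at 0.44, 0.75 and 0.22 in the same order. Mug1 was at 1.20 without standard array 10 alone and 1.15 without the 3 arrays that stood apart, where Plg was at 0.64. Fgb was at 0.16 with arrays centred on their median. The magnesium transport list was not called (mean 0.17, adjusted p = 0.436, 5 of 6 higher). Within it Magt1, a magnesium transporter that is also a subunit of an oligosaccharyltransferase complex, was 0.73 ± 0.31 (SE) higher (adjusted p = 0.518), Egf was at 0.17 ± 0.24 and Nipal2 at 0.15 ± 0.26. With the Gapdh ratio as a covariate Magt1 was at 0.35, Nipal2 at 0.050, Egf at -0.0036 and the list mean at 0.11. With the beta-actin ratio Magt1 was at 0.41 and Egf at 0.043. With values as deposited the list mean was 0.27, Egf was at 0.32 and Nipal2 at 0.27. With 1 array left out Egf ranged from 0.084 (supplemented array 2) to 0.33 (supplemented array 4), and Nipal2 from -0.023 (supplemented array 4) to 0.29 (supplemented array 2). Both were smaller than their SE and moved widely in other settings too.

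The widest contrast in dietary magnesium, deficient against supplemented, gave the only call on a single gene. Crispld2 was 3.80-fold higher on the deficient than on the supplemented diet, a log2 difference of 1.93 ± 0.28 (SE; limma adjusted p = 0.0232). Its log2 signal was 3.24 ± 0.30 (SD, n = 5) on the supplemented, 4.94 ± 0.41 (SD, n = 5) on the standard and 5.17 ± 0.43 (SD, n = 4) on the deficient diet. Each of the 5 supplemented arrays lay below each of the other arrays and under the level of the dim-probe filter. The F-test over the 3 diets also called 1 probe set, that of Crispld2 (adjusted p = 0.0242), with 460 at an unadjusted p under 0.05. Among other settings, the call was lost with values as deposited (adjusted p = 0.226), arrays centred on their median (0.12), no filter (0.071) or only the 2 diets in the fit (0.128), and without supplemented array 1, 3 or 4, standard array 8 or deficient array 11, 12 or 13. Over these 7 runs the adjusted p reached 0.166 without deficient array 13. The difference itself lay between 1.52 and 2.08 in all 26 alternatives that measured it.

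**Figure D3:**
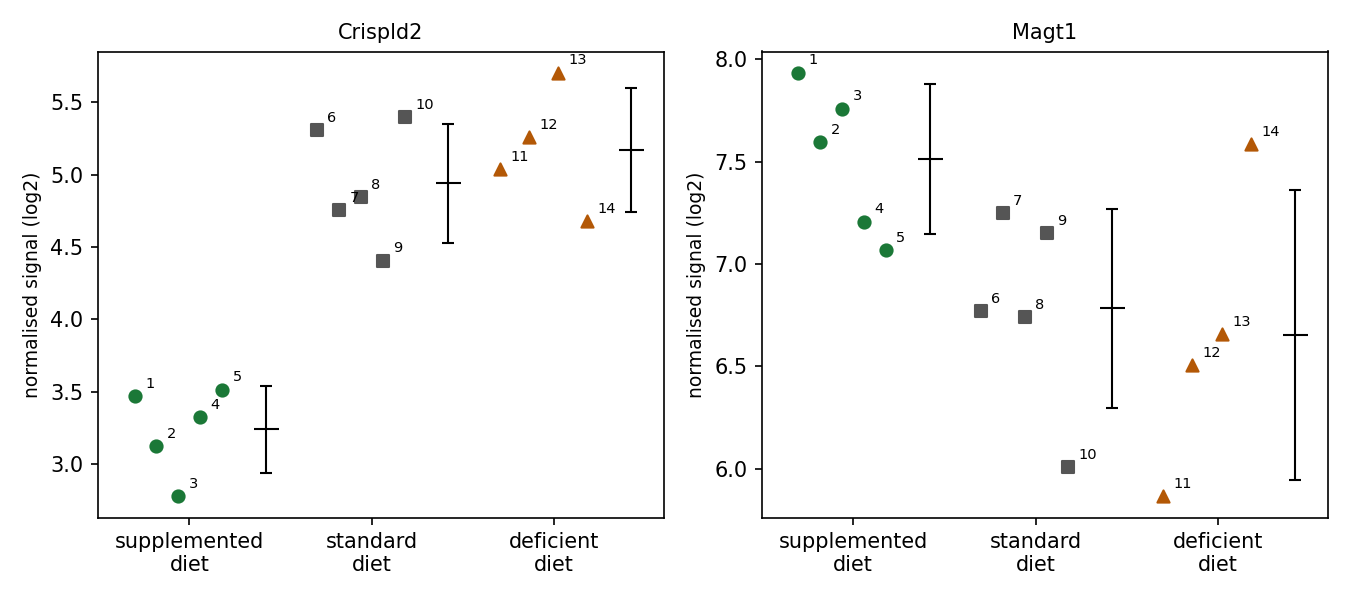
Normalised log2 signal of Crispld2 (left) and Magt1 (right) on each array by diet, with the mean and SD as bars. Crispld2 lay between 2.78 and 3.52 on the supplemented arrays and between 4.41 and 5.70 on the others, and Magt1 averaged 7.51 on the supplemented and 6.65 on the deficient diet.

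The magnesium transport list differed between these diets by a mean of -0.29, with 5 of 6 genes lower on the deficient diet. It was not called by camera (adjusted p = 0.267; adjusted p = 0.941 with an estimated correlation), while fry, which asks only whether the genes move one way on balance, gave an adjusted p of 0.0310. The list's score was -0.15 ± 0.05 (SD, n = 4) on the deficient and 0.14 ± 0.06 (SD, n = 5) on the supplemented diet, without overlap (exact permutation p = 0.00794, the smallest this design can give, and 0.317 adjusted over 40 lists). Magt1 was lower on the deficient diet by a log2 difference of -0.86 ± 0.32 (SE; limma adjusted p = 0.327). Egf stood at -0.32 ± 0.25 and Slc41a3 at -0.31 ± 0.33, and the latter turned to 0.14 without deficient array 14 and was at -0.54 without deficient array 11. Without these arrays, in the same order, Egf was at -0.55 and -0.20. With the Gapdh ratio as a covariate the mean of the list was -0.21 (adjusted p = 0.420), Magt1 was at -0.39, Egf at -0.10 and Slc41a3 at -0.65. With the beta-actin ratio these 3 genes were at -0.34, -0.11 and -0.64. Values as deposited put Egf at -0.52 and Slc41a3 at -0.58, and array weights put them at -0.50 and -0.11. Slc41a3 was at -0.48 with arrays centred on their median. In this list 0 genes passed when adjusted over the list alone.

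At an unadjusted p under 0.05 there were 663 of 5132 probe sets between the deficient and the supplemented diet, or 12.9%, against 256.6 by chance. Of these, 347 were higher and 316 lower on the deficient diet. With the Gapdh 3'/5' ratio as a covariate 113 were left and Crispld2 was no longer called. Without deficient array 13 there were 395. Besides Crispld2 the smallest p belonged to Tor1aip1, a protein of the nuclear envelope, at 0.99 ± 0.22 (SE), Slc7a2 at 1.08 ± 0.24, Mgat2, a glycosyltransferase gene, at -1.14 ± 0.27 and Nrp1 at 0.73 ± 0.17. None of these 4 passed over all probe sets (adjusted p between 0.212 and 0.216). All 40 lists were without a call, among them cholesterol synthesis (mean 0.11, adjusted p = 0.921, 11 of 15 higher), and 3 genes passed when adjusted over their own list alone. These were Slc7a2 in the amino acid list (adjusted p = 0.0188), Egfl7 in the endothelial list (adjusted p = 0.0331, log2 difference 1.65 ± 0.47) and Slc4a2 in the bile duct list (adjusted p = 0.0467, log2 difference 0.65 ± 0.20). Each of the 40 lists was adjusted on its own, so a few such genes can pass by chance. Over all probe sets none of the 3 passed (limma adjusted p = 0.216 for Slc7a2, 0.253 for Egfl7 and 0.263 for Slc4a2). The Gapdh ratio as a covariate put Tor1aip1 at 0.62, Egfl7 at 1.00 and Slc4a2 at 0.30, and the beta-actin ratio put Tor1aip1 at 0.60 and Slc4a2 at 0.36.

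Other members with the smallest p of their lists did not pass. On the deficient diet Mx2 was at -1.59 ± 0.46 (SE), the endoplasmic reticulum disulfide isomerase gene Pdia4 at -0.84 ± 0.26, Ugt1a5 at -1.46 ± 0.57, Gsta1 at -0.39 ± 0.13, Cyp2c22 at -0.64 ± 0.20, Scd2 at -0.94 ± 0.34 and the proteasome gene Psma1 at -0.61 ± 0.22. Higher values were seen for the calcium entry channel gene Orai1 at 0.95 ± 0.31, Tgfb1 at 1.31 ± 0.49, the coagulation factor gene F10 at 0.80 ± 0.28, Gckr at 0.59 ± 0.23, Stmn1 at 0.69 ± 0.22, the mitochondrial thiolase gene Acaa2 at 0.49 ± 0.14 and Apoc4 at 0.59 ± 0.18. Ddit3 was 2.83-fold higher, with an SE of 0.48 on the log2 scale. Mug1 was at -1.97 ± 0.79 and turned to 0.31 with the Gapdh ratio as a covariate. Many of these values shrank with that covariate: F10 to 0.065, Gckr to 0.15, Apoc4 to 0.17, Orai1 to 0.57, Ddit3 to 0.67, Pdia4 to -0.39, Ugt1a5 to -0.42, Gsta1 to -0.21, Cyp2c22 to -0.43 and Psma1 to -0.21. With the beta-actin ratio Mug1 was at -0.19, Ugt1a5 at -0.52, Gsta1 at -0.23 and Psma1 at -0.35. Single arrays mattered for Mx2 and Scd2, at -0.999 and -0.55 without deficient array 11, and for F10, at 0.51 without supplemented array 5. Scd2 was at -0.52 with only the 2 diets in the fit. Without the 3 arrays that stood apart Mug1 was at -1.28, F10 at 0.47, Orai1 at 0.62 and Apoc4 at 0.39.

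The comparisons of the deficient and the supplemented diet with the standard diet had 0 called probe sets in common. Across probe sets, which are not independent replicates, their log2 differences correlated with Pearson's r = 0.183. Unchanged diets that share the standard arrays gave a mean r of 0.467 in simulation (95% between 0.0960 and 0.750), and the covariance was 0.0223 against a simulated 0.0612. With the standard arrays split so that each comparison had its own, r averaged -0.15 over 20 splits (from -0.43 to 0.10). The same direction was seen for 53.4% of probe sets, against a simulated 65.8%. At an unadjusted p under 0.05 in both, 21 probe sets went the same way and 3 went opposite ways. Unchanged diets that share the standard arrays gave a mean of 44.6 and 0.58 in 100 simulations, so the 21 are no excess (95% of the simulated counts of the same direction lay between 0.475 and 141.1).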

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

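The tests of RNA quality and of a single array for Crispld2 were chosen after the results or values that bear on them had been seen. So were the covariates of beta-actin ratio and Cyp2c12 level. The other tests weighed here were set out before. For Crispld2, the end of its call with the Gapdh ratio and its signal on each array were already known. Within each diet, a sample was picked out when its gap to the nearest other sample took up most of that diet's range, which chance gives in about 5% of diets. It did so for 2 of 18 diets over the array measures, 2 of 18 over the list scores and 15 of 258 over 86 named genes.

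Supplemented array 5 stood apart from the other supplemented arrays in the share of signals at the floor (13.6%, others 19.6% to 21.3%) and in its mean rank correlation with the other arrays (0.913, others 0.945 to 0.951). It also did so in the score of neighbouring tissue markers (0.68, others -0.20 to 0.03) and in log2 signals of Lep (9.63), Hdac6 (5.22), F10 (9.33) and Nrp1 (4.95). The ribosomal protein score was 0.15 on supplemented array 4, against -0.13 to -0.07 on the others, and that array had Stip1 at 5.25. Supplemented array 1 had Rpl36 at 10.12, and supplemented array 2 had Lrrc8a at 5.45 where the other 4 were at the floor. Standard array 10 stood apart for Mug1 (5.64), Plg (8.28) and Ssh3 (3.07), and standard array 7 for Lrrc8a (3.97). On the deficient diet, array 11 stood apart for Cish (6.78), array 12 for Mgat2 (4.13) and array 14 for Plin2 (11.31) and F10 (10.72).

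The most probe sets at an unadjusted p under 0.05, 663, lay between the deficient and the supplemented diet. Supplemented array 5 is argued against as the cause, since 638 were left without it, far above 1.5 times the chance count. A difference in RNA quality may account for part or all of these differences. Of the 663, 90.6% had a slope on the Gapdh 3'/5' ratio within diets of the sign that the ratio difference between the diets would need. Among all probe sets tested this share was 73.6%. The count was 113 with the ratio as a covariate, under the 256.6 that chance gives. The change that the slope predicts had a median of 0.517 of the size of the difference. This does not show how much is left over, since the 663 were picked for large differences and the slope carries error. Chance cannot be excluded either, since 5 of 100 splits of these 9 arrays gave as many, and the highest other split gave 809. An effect of diet on these probe sets, or on the RNA quality itself, stays open, because the ratio and the diet go together here.

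Cholesterol synthesis genes were lower on the standard diet than on the deficient diet by a mean of 0.52, and lower than on the supplemented diet by 0.41. Between the deficient and the supplemented diet the mean difference was 0.11, without a call (adjusted p = 0.921). Both shifts have the same 5 standard arrays as their reference. These were spread widely, with scores of -1.04 on array 8 and -0.74 on array 7 but 0.44 on array 9. For the deficient diet, RNA quality is argued against as the cause only as far as the Gapdh ratio measures it. That ratio differed from the standard diet by 0.21 (exact permutation p = 0.595), and the beta-actin ratio by 0.33 (exact permutation p = 0.516). With so few arrays these p-values cannot exclude a difference in quality. The shift was 0.53 with the Gapdh ratio as a covariate, which adds little because so small a difference left little to remove. For the supplemented diet, whose Gapdh ratio was lower by 0.93, RNA quality stays open. There the beta-actin ratio as a covariate took Idi1 from 1.08 to 0.52 and Sqle from 0.95 to 0.53. The list as a whole was still called with either ratio as a covariate, at camera's preset correlation. A state of single samples unrelated to diet, such as recent feeding, and an effect of the diet stay open. Feeding was not tested. The level of Cyp2c12, typical of female liver, was tried as a covariate. It made both shifts smaller and ended the supplemented call, as given under other observations. Among standard arrays its log2 signal was highest on array 9 (9.09) and lowest on arrays 7 and 8 (4.05 and 4.76). Deficient array 14, with the highest cholesterol score of all arrays (0.59), had Cyp2c12 at 4.78.

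Crispld2 was lower on the supplemented diet than on the deficient diet by 1.93 ± 0.28 (SE). No single array carries the difference, whose lowest value with 1 array left out was 1.74. RNA quality as the whole cause is argued against, since the difference was 1.52 ± 0.34 (SE) with the Gapdh ratio as a covariate, although the call ended. The unadjusted p went from 4.52e-06 to 0.000526 through a smaller difference and a larger error, and the smallest adjusted p of any probe set was then 0.9999. Chance cannot be excluded, as 10 of 100 splits of the 9 arrays called as many probe sets, with 4 in the highest other split. An effect of dietary magnesium on Crispld2 is a hypothesis that these arrays leave open.

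Counts in the other comparisons were also set against other splits. Where the real count is 0 every split reaches it (100 of 100), so those counts say nothing about chance. They are the called probe sets for deficient against standard (highest other split 87, median of the others 0) and for supplemented against standard (highest other 2), and the lists for deficient against supplemented (highest other 9). For deficient against standard, at an unadjusted p under 0.05, 65 of 100 gave at least the real 154 (highest other 816), and 30 of 100 called at least the real 4 lists (highest other 8). For supplemented against standard, 10 of 100 gave at least the real 457 at an unadjusted p under 0.05 (highest other 686) and 73 of 100 at least the real 2 lists (highest other 9). Across the 3 diets, 7 of 100 splits called at least the real 1 probe set (highest other 14) and 8 of 100 gave at least the real 460 at an unadjusted p under 0.05 (highest other 782). Chance cannot be excluded for any of these counts above 0.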

How the results depend on the processing

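The covariates of beta-actin ratio and Cyp2c12 level, and the run without 3 arrays that stand apart (supplemented 5, standard 10 and deficient 13), were chosen after seeing the data. A run without standard arrays 7 and 8 was also made after seeing the data and is not reported, as they were picked for their low cholesterol scores. All other alternatives were planned. No paired analysis was possible because the diets share no array number. Filters on dim probe sets do not bear on the control probe sets, so they were not run for RNA quality. Unless stated, the cause of a change was not tested.

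Between the deficient and the standard diet 0 probe sets were called in every setting, including each of 14 runs with 1 array left out. Between the supplemented and the standard diet the count of 0 became 1 without a trend of the spread on the mean and with array weights, and ran from 0 to 2 with 1 array left out (2 without supplemented array 2; 1 without standard array 9, deficient array 13 or deficient array 14). Between the deficient and the supplemented diet the count of 1 became 0 with values as deposited, arrays centred on their median, no filter, the filter at the 60th percentile, only the 2 diets compared, the Gapdh ratio, the beta-actin ratio or the Cyp2c12 level as a covariate, and without 3 arrays that stand apart. It ran from 0 to 4 with 1 array left out (0 without supplemented array 1, 3 or 4, standard array 8, or deficient array 11, 12 or 13; 3 without supplemented array 2; 4 without deficient array 14). At the 60th percentile Crispld2 is itself filtered out. Across the 3 diets the count of 1 became 0 with values as deposited, arrays centred on their median, no filter, the filter at the 60th percentile, the Gapdh ratio, the beta-actin ratio, the Cyp2c12 level, and without the 3 arrays, and ran from 0 to 3 with 1 array left out (3 without supplemented array 2, 2 without deficient array 14, 1 without supplemented array 5 or standard array 9, otherwise 0). Crispld2 kept its direction in all 26 settings that measured it and was called in 11 of them (adjusted p from 0.0035 to 0.9999).

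At an unadjusted p under 0.05 the 154 probe sets for deficient against standard became 324 with no filter, 86 with the filter at the 60th percentile, 237 with array weights and 92 without deficient array 13. The 457 for supplemented against standard became 132 with the Gapdh ratio, 247 with the beta-actin ratio, 270 without 3 arrays that stand apart and 287 without standard array 10. The 663 for deficient against supplemented became 113 with the Gapdh ratio, 245 with the beta-actin ratio, 996 with array weights and 395 without deficient array 13.

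The 4 lists called for deficient against standard became 1 with arrays centred on their median and 0 with an estimated correlation and with fry; with 1 array left out they ran from 1 (standard array 9) to 6 (deficient array 14), with 2 without standard array 6 or deficient array 13. The 2 lists for supplemented against standard became 4 with values as deposited, with arrays centred on their median and with array weights, 1 with the filter at the 60th percentile, and 0 with an estimated correlation, fry and the Cyp2c12 level; with 1 array left out they ran from 0 (standard array 8) to 4 (supplemented array 5), with 1 without supplemented array 1 or 4 or standard array 6. The 0 lists for deficient against supplemented became 1 with values as deposited, arrays centred on their median, only the 2 diets compared, fry, the mean of all probe sets of a gene and the beta-actin ratio, and 2 with array weights, the Gapdh ratio and without 3 arrays that stand apart; with 1 array left out they ran from 0 to 3 (supplemented array 5), with 1 without supplemented array 4, standard array 10 or deficient array 14. Against standard, cholesterol synthesis was called in 28 of 30 settings (deficient) and 26 (supplemented). Ribosomal proteins had 25 calls, heat shock 21, neighbouring tissue 12 and macrophages 20. Without the preset correlation none was called. Directions held in all 30.

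The correlation of 0.18 between the comparisons with the standard diet became 0.35 with the Gapdh ratio and ran from -0.00636 (deficient array 14) to 0.38 (standard array 9) with 1 array left out. The beta-actin ratio difference between the deficient and the supplemented diet was 0.89 after quantile normalisation too, with an exact permutation p of 0.0556 in place of 0.0476. With the Gapdh ratio as a covariate Egf (-0.0036, supplemented minus standard), Plg (-0.031) and Mug1 (0.31, deficient minus supplemented) reversed. So did Nipal2 (supplemented minus standard) without supplemented array 4, with a range of -0.023 to 0.29 over single arrays left out, and Slc41a3 without deficient array 14, with ranges of -0.67 to 0.023 against standard and -0.54 to 0.14 against supplemented. Hspb1 reversed (0.052) without the 3 arrays that stand apart. The other named genes kept their direction in every setting: 30 of 32 followed for deficient against standard, 36 of 39 for supplemented against standard and 28 of 30 for deficient against supplemented.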

Other observations

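The genes, the test and its bounds in this part were chosen after their values were seen. Genes that differ between male and female rats varied widely between arrays of a diet. Cyp2c12, a P450 typical of female rat liver, had log2 signals of 10.33 and 9.46 on supplemented arrays 3 and 4, 9.09 on standard array 9, and 8.93 and 8.87 on deficient arrays 11 and 13. On the other 9 arrays it lay between 4.05 (standard array 7) and 7.26 (supplemented array 2). Cyp2c11, typical of male liver, was at 8.51, 8.98, 9.74, 10.75 and 11.00 on those same 5 arrays, in that order. It lay between 11.45 (deficient array 12) and 12.39 (supplemented array 5) on the others. Cyp3a2, another gene typical of males, was at 6.71, at the floor of 1.97, and at 6.20, 8.16 and 9.10 on the 5 arrays and between 9.41 and 10.86 elsewhere. The score of the male-predominant list was also lowest on these 5 arrays, though deficient array 13 (-0.16) lay close to deficient array 12 (0.026). The female-predominant list did not single them out. Its score was 0.57 on supplemented array 2, above supplemented array 4 (0.39) and deficient arrays 11 (0.34) and 13 (0.16). The labels give no sex, so no groups were formed from them.

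A candidate explanation is that the series holds livers of both sexes, or of animals that differ in growth hormone secretion. No test here decides between these. Whether such a difference hides effects of diet was tried by adding the Cyp2c12 level as a covariate. With it limma called 0 probe sets in each comparison, and 686 were at an unadjusted p under 0.05 between the deficient and the supplemented diet against 663 without it. This small rise lies between the bounds set for the test, so it stays open whether effects of diet are hidden. With the covariate the cholesterol synthesis shift was 0.43 in place of 0.52 for deficient against standard, still called (adjusted p = 6.99e-06). For supplemented against standard it was 0.28 in place of 0.41 and no longer called (adjusted p = 0.130).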
